A study of Mus musculus with 8 samples.

How the data were processed

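Whole corneas of male C57BL/6J mice were profiled by RNA sequencing. Per the labels, the mice were adrenalectomized at 8 weeks of age, which removes their own source of glucocorticoids, and about 4 weeks later received eye drops with dexamethasone, a synthetic glucocorticoid, or with vehicle for 6 h. Each group had 4 libraries, and each library was made from the total RNA of 4 to 6 pooled corneas. The labels describe paired-end reads of 75 bp and more than 40000000 reads per sample. The replicates are separate pools, and the labels do not say from how many mice each pool came.

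Per the submitters' processing notes, Bowtie2, HTSeq and DESeq2 were used with the mouse genome build mm9. Their versions, the gene annotation, the strand setting and the exact transformation are not given in the sources used here. The deposited table holds log2 normalized values made by the authors, with 24918 rows, each a gene locus named by symbol and Entrez identifier, and a column for each of the 8 libraries. No column was left unused. Whole reads could not be recovered from these values, so the read total behind each value is unknown and no counting interval is given. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The alpha and beta globin genes were listed at 0 in all 8 libraries, among 5078 such rows, so a value of 0 is reported only as listed at 0.

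The form of the values limits what they can show. Among the 812 rows with a mean of 2 to 3, the median SD within groups was 0.021, whereas a Poisson count of 8 would have an SD of 0.51 on the log2 scale. The values therefore behave as shrunken log2 values, as a regularized log transformation gives, and fold changes are understated, most of all for genes with low values. The transformation was inferred from the values and is not named in the labels. All fold changes below are differences of these log2 values, or 2 raised to such a difference.

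Genes were tested with limma 3.58.1 in R 4.3.3 on the log2 values (linear model on group, empirical Bayes moderation with a trend over expression level, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 14715 rows with a mean of at least 3. A gene was called at an adjusted p below 0.05. Errors of group means are SDs over 4 libraries, and errors of log2 fold changes are the moderated standard errors. A total of 35 gene lists were written from textbook knowledge before the data were examined. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over these lists, beside camera with an estimated correlation and fry. The list tests were first run without a variance trend and then with it, to match the gene-wise fit. Both versions are reported in the closing section, because the choice was made after results had been seen: 8 lists were called with the trend and 7 without it. Another 6 lists were written after the data were seen, and these are given as counts and medians, with no camera or fry test. Exact permutation tests, outlier ratios and coordinates were computed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Coordinates were taken by symbol from GENCODE vM1 on NCBIM37, the assembly of mm9; 116 of 118 symbols matched a single gene.

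The rule for named genes was fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 and no overlap between the groups, up to 4 called members of each list by adjusted p (or up to 2 by level in a list with none), and a set of genes named in advance. Of that set, Il1b was not tested, with a mean of 2.63. Genes named outside the rule are marked as such. Some genes that the rule takes are not reported here. The gene-wise fit was checked on simulated data with the real levels and spreads of the 14715 genes for dexamethasone against vehicle. Of 50 changed genes per size, 10% were called at a log2 change of 0.1, 70% at 0.2, 96% at 0.4 and 98% at 0.8. Of 147 calls 10 were false. Only 200 genes were changed there, against 2218 called in the data, so the adjusted threshold was stricter. The simulated noise was also independent between genes, without differences shared by a library. These rates therefore do not give the sensitivity of the real comparison.

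Alternatives fixed in advance were a replicate block, no filter and a stricter filter of at least 5, a pseudocount of 8, quantile normalization, median centring, limma without trend, robust moderation, library quality weights, leaving out each library in turn, camera with an estimated correlation, fry, and the glucocorticoid receptor target list without genes shared with other lists. Count tests on whole reads were planned and not run, because the values are not counts.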

Results

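RNA from whole corneas was compared between 4 libraries after dexamethasone eye drops and 4 libraries after vehicle drops, in adrenalectomized male mice at 6 h. The comparison asks which corneal genes respond to a glucocorticoid applied to the eye when the adrenal supply has been removed. The values are the authors' normalized log2 values. The depth of single libraries is unknown, beyond the statement in the labels that it exceeded 40000000 reads per sample.

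Known targets of the glucocorticoid receptor separated the groups in every library. Fkbp5 (Entrez 14229; mm9 chromosome 17, 28536040 to 28654469), a co-chaperone of steroid receptors, had a log2 value of 14.50 ± 0.05 (SD, n = 4) after dexamethasone and 13.62 ± 0.12 (SD, n = 4) after vehicle, a 1.84-fold rise (adjusted p = 3.43e-06, limma). Its lowest dexamethasone library stood at 14.47 and its highest vehicle library at 13.73. Tsc22d3 (Entrez 14605; chromosome X, 137074067 to 137135198), which encodes the glucocorticoid-induced leucine zipper protein, was 13.59 ± 0.09 (SD, n = 4) against 13.00 ± 0.03 (SD, n = 4). Per1 (Entrez 18626; chromosome 11, 68908719 to 68923462), a clock gene, was 12.62 ± 0.03 (SD, n = 4) against 12.20 ± 0.07 (SD, n = 4). All 3 genes lay higher in the 4 dexamethasone libraries than in the 4 vehicle libraries. The receptor gene itself, Nr3c1, was 11.24 ± 0.04 (SD, n = 4) after dexamethasone and 11.32 ± 0.01 (SD, n = 4) after vehicle, which did not pass the threshold (adjusted p = 0.0692, limma); it passed under quantile normalization (0.037) and with library quality weights (0.040).

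**Figure D1:**
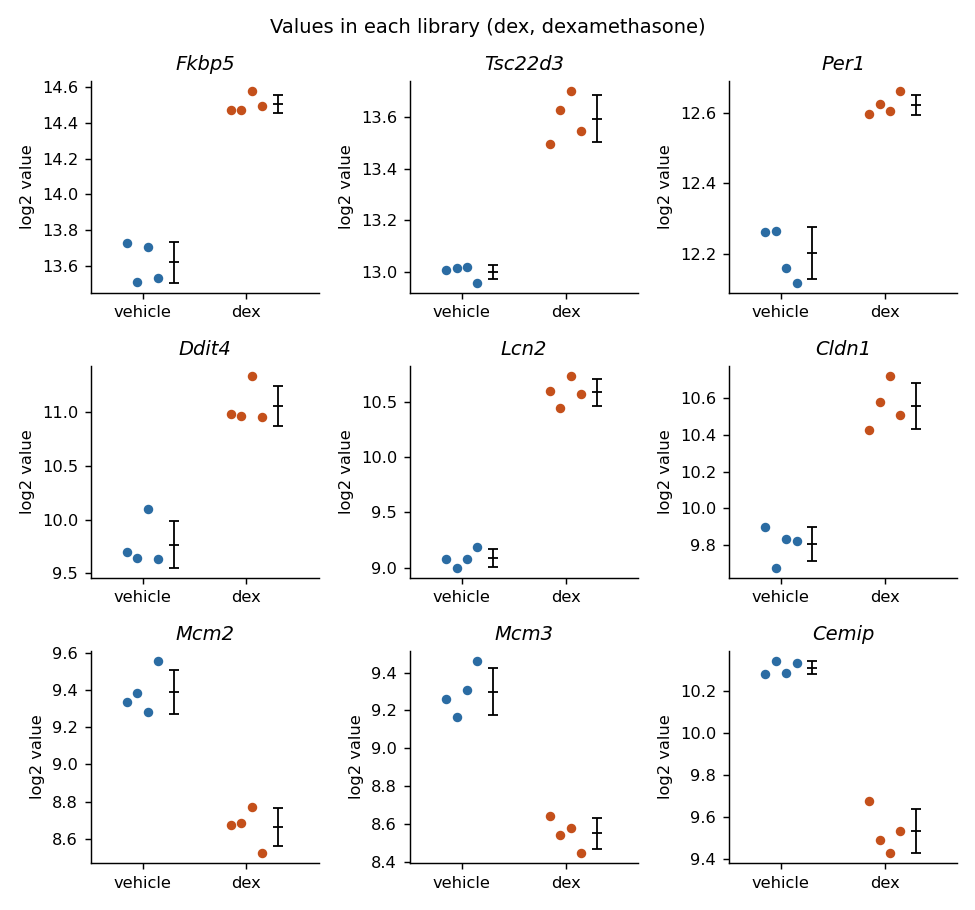
Log2 values (vertical axes, which do not start at 0) of 9 genes in the vehicle and dexamethasone groups. Points are libraries, and bars are the mean and SD of 4 libraries. In all 9 genes the 4 dexamethasone libraries lie entirely above or entirely below the 4 vehicle libraries.

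Spsb1, Lcn2 and Ddit4 rose most. Spsb1 (Entrez 74646; chromosome 4, 149270392 to 149329152), an adaptor of a ubiquitin ligase, rose from 9.17 ± 0.03 (SD, n = 4) to 10.76 ± 0.19 (SD, n = 4), or 3.02-fold (log2 fold change 1.60, SE 0.07, adjusted p = 1.17e-06, limma). Lcn2 (Entrez 16819; chromosome 2, 32240153 to 32243317), a secreted iron-siderophore binding protein, rose 2.83-fold. Ddit4 (Entrez 74747; chromosome 10, 59412423 to 59414518), an inhibitor of mTORC1 signalling, rose 2.45-fold. The metalloprotease-related genes Adamtsl2 and Adamts14, the deubiquitinase gene Usp2, the fucosyltransferase gene Fut4, the channel gene Best2 and the matrix-associated growth factor gene Ctgf rose 1.86- to 1.96-fold. Falls were smaller. Cemip, which encodes a hyaluronan-degrading protein, had a log2 fold change of -0.78 (SE 0.05, adjusted p = 3.69e-06, limma). The replication helicase genes Mcm3, Mcm2, Mcm5 and Mcm6 had log2 fold changes of -0.75, -0.72, -0.71 and -0.54. Tacr3, a tachykinin receptor gene, had -0.59, Chst5, a sulfotransferase gene of keratan sulfate synthesis, -0.55, Hells, a chromatin remodeller gene, -0.55, Vsnl1, a calcium sensor gene, -0.52, and Uhrf1, a gene for maintenance of DNA methylation, -0.50.

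**Figure D2:**
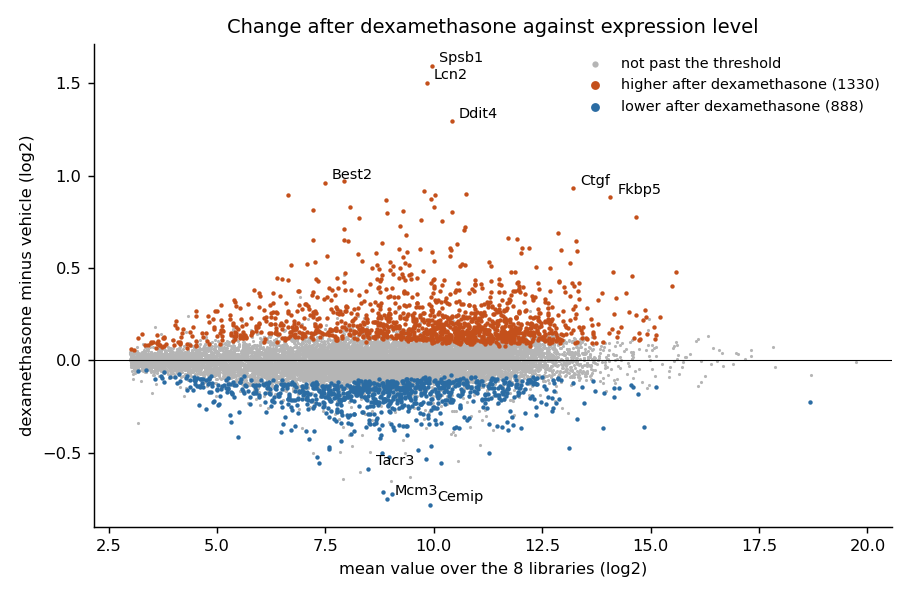
Difference between the groups (vertical axis, dexamethasone minus vehicle, log2) against the mean value over the 8 libraries (horizontal axis, log2) for the 14715 tested rows. Coloured points are the 1330 genes called higher and the 888 called lower, and the largest rise is Spsb1 at 1.60.

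In all, 2218 of 14715 tested rows changed, 1330 higher and 888 lower. The changes were small on this shrunken scale: the median log2 fold change was 0.18 among the risers and -0.17 among the fallers, 83 genes reached an absolute value of 0.5, of which 71 rose, and 3 reached 1. The groups did not overlap in 3047 rows, or 20.7% of those tested, where chance gives 2.86%. Without dexamethasone replicate 4, 1537 genes were called with 547 lower, and without vehicle replicate 4, 1411 were called with 493 lower. With a term for the level each library shows in rows without a read, added after the data were seen, 1168 were called.

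The list of glucocorticoid receptor targets rose as a group. Of its 32 tested members 25 rose and none fell, with a median log2 fold change of 0.39 (adjusted p = 4.34e-25, camera with limma-trend), and 27 rose when adjusted over the list alone. The adjusted p was 0.103 with an estimated correlation and 0.000153 with fry. Among the members were Zbtb16, a zinc finger transcription factor gene (0.80), Klf15, a Kruppel-like factor gene (0.63), and Nfkbia, the gene of the NF-kB inhibitor IkB-alpha (0.38). The 27 targets not shared with another list held 20 risers and no faller, with a median of 0.40.

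In the cell cycle list 12 of 32 tested members fell and 1 rose, and 12 fell and 2 rose when adjusted over the list alone (adjusted p = 0.0181, camera; direction down). The adjusted p was 0.865 with an estimated correlation, 0.0767 with fry and 0.0921 without vehicle replicate 1. The fallers were the helicase genes Mcm2 to Mcm7, Pcna, Rrm2 and Tyms, which serve DNA and nucleotide synthesis, the cyclin genes Ccne1 and Ccne2, and Kif23, a kinesin gene of cytokinesis. Ube2c, a ubiquitin-conjugating enzyme gene of mitotic exit, rose by 0.19; 2 members rose without dexamethasone replicate 2 or vehicle replicate 1. Those outside the rule for named genes were named after their values were seen. The list mean was -0.12 and its median 0.01, so median and test differed in sign.

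In the list of matrix proteases and wound matrix genes 12 of 33 tested members rose and 1 fell, against 13 and 1 adjusted over the list alone (adjusted p = 0.00275, camera), with an adjusted p = 0.615 with an estimated correlation and 0.0129 with fry; the other 20 were not called. Ctgf rose by 0.93 (SE 0.06) and Lox, which encodes a collagen cross-linking enzyme, by 0.61 (SE 0.06). Spp1, which encodes osteopontin, rose by 0.49, and Plau, the urokinase gene, had a log2 fold change of -0.34. Of 19 clock genes 7 rose, none fell and 12 were not called, with 8 rising adjusted over the list alone (adjusted p = 0.00976, camera, and adjusted p = 0.248 with an estimated correlation and 0.00283 with fry). The risers included Per1 and Npas2 (0.29, SE 0.05). Their number was 3 without dexamethasone replicate 1 or vehicle replicate 4, and 4 without dexamethasone replicate 3 or 4 or vehicle replicate 2, with a replicate block, with quantile normalization or with no filter.

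**Figure D3:**
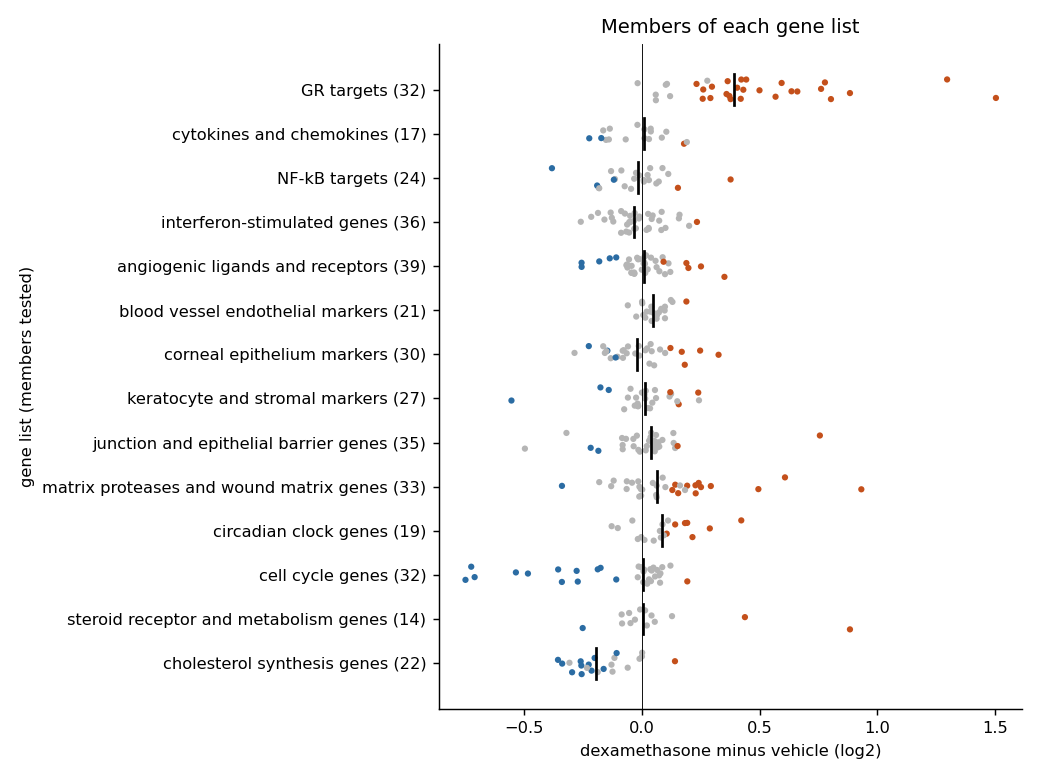
Log2 fold changes (horizontal axis, dexamethasone minus vehicle) of the tested members of 14 gene lists (vertical axis; GR, glucocorticoid receptor). Points are genes, orange for called higher, blue for called lower and grey for not called, and black bars are list medians. The median is 0.39 for the glucocorticoid receptor targets and -0.19 for cholesterol synthesis.

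None of the inflammatory lists passed the camera test, which looks for a common direction. For scale, 15.1% of all tested rows were called. Fry without regard to direction asks whether members change at all. Its adjusted p was 1.77e-07 for cytokines and chemokines, 4.81e-05 for NF-kB targets and 0.175 for interferon-stimulated genes. Among 17 tested cytokines and chemokines Cxcl5 (-0.22) and Il18 (-0.17) fell and Lif (0.18) rose (adjusted p = 0.584, camera), with 3 higher and 4 lower adjusted over the list alone, and 2 higher without vehicle replicate 3. The other members of this list of 37, among them Il1b, Il6, Cxcl10 and Ccl2, had means below 3 and were not tested. Cxcl12 was 7.65 ± 0.02 (SD, n = 4) against 7.57 ± 0.16 (SD, n = 4). Among 24 NF-kB targets 2 rose, Nfkbia and Nfkb1 (0.15), and 3 fell (adjusted p = 0.843, camera). None fell without dexamethasone replicate 3 or 4 or vehicle replicate 4, or with the term for rows without a read, and 1 fell without dexamethasone replicate 1 or vehicle replicate 2 or 3, with a replicate block or with no filter. Among 36 interferon-stimulated genes only Isg20 rose (0.23) and none fell (adjusted p of the list 0.537, camera); 2 rose without dexamethasone replicate 3, 1 fell without vehicle replicate 2, and 2 fell with a replicate block.

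Of 39 angiogenic ligands and receptors 5 rose and 5 fell (adjusted p = 0.969, camera), and 3 rose without dexamethasone replicate 2 or vehicle replicate 1 or 4. Notch4 (0.35) and Timp3, an inhibitor of metalloproteases (0.25), rose, and Fgf1 (-0.26) and Apln (-0.14) fell. Vegfa was 9.93 ± 0.38 (SD, n = 4) against 9.99 ± 0.45 (SD, n = 4). It stood at 10.48 in dexamethasone replicate 1 and 10.65 in vehicle replicate 3, against 9.62 to 9.87 in the other libraries. In the blood vessel list 1 of 21 members was called, Tie1 (0.19), with adjusted p = 0.0568 for the list (camera). The list passed with a replicate block (0.0301), no filter (0.0327), quantile normalization (0.0282) or median centring (0.0455), and without dexamethasone replicate 1 (0.0401) or 3 (0.0111) or vehicle replicate 4 (0.00424), and its adjusted p was up to 0.313 on leaving out another library, 0.447 with the term for rows without a read and 0.865 with an estimated correlation. Pecam1 was 7.29 ± 0.14 (SD, n = 4) against 7.16 ± 0.10 (SD, n = 4) and did not pass. The call for Tie1 was lost in 5 alternatives, among them those without dexamethasone replicate 2 or vehicle replicates 1, 2 or 4 (adjusted p of 0.050 to 0.055, limma).

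None of the marker lists of the corneal layers passed the camera test, which looks for a common direction. Their called members moved both ways. Of all tested rows 15.1% were called. With fry without regard to direction the adjusted p was 1.31e-06 for epithelial, 3.21e-06 for stromal and 3.21e-06 for corneal endothelium markers. In the epithelial list 5 of 30 rose and 3 fell (adjusted p = 0.969, camera), against 3 risers without vehicle replicate 4 and 6 fallers with quantile normalization. Clu, which encodes the chaperone clusterin, rose by 0.33 and Klf5 by 0.25, and Krt5, a basal keratin gene, had -0.23, a call lost under quantile normalization (adjusted p = 0.267, limma). Krt12, the corneal keratin gene, was 19.73 ± 0.06 (SD, n = 4) against 19.74 ± 0.02 (SD, n = 4), and Pax6 was 14.40 ± 0.05 (SD, n = 4) against 14.35 ± 0.07 (SD, n = 4). In the stromal list 3 of 27 rose and 3 fell (adjusted p = 0.794, camera), among them Chst5, Lum (-0.18) and Cd34 (0.24). Kera, a keratan sulfate proteoglycan gene, had -0.14, a call lost in 6 alternatives. Among these were the fits without dexamethasone replicate 2 or 4 or vehicle replicate 2 or 4 (adjusted p of 0.065 to 0.073, limma). In the junction and barrier list 2 of 35 rose and 2 fell (adjusted p = 0.353, camera), with Cldn1, a tight junction gene (Entrez 12737; chromosome 16, 26356728 to 26371927), at 0.76 (SE 0.06) and Cldn8 at -0.22. In the list of steroid receptor and metabolism genes Fkbp5 and H6pd (0.44) rose and Ptges3 (-0.25) fell, of 14 tested (adjusted p = 0.584, camera). Ptges3 lost its call in 2 alternatives, among them that without vehicle replicate 4 (adjusted p = 0.053, limma).

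Dexamethasone replicate 1 and vehicle replicate 3 stood apart from the other libraries. They had the highest scores on the second principal component (23.3% of the variance), while the first (47.0%) separated the treatment groups. Keratinocyte genes known from wounded epithelium were high in both, chosen after the values were seen: Krt16 was 9.33 in dexamethasone replicate 1 and 11.20 in vehicle replicate 3, against 7.33 to 8.04 in the other libraries. The number of called genes without both libraries was 2202, of which 1797 were shared with the 2218.

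**Figure D4:**
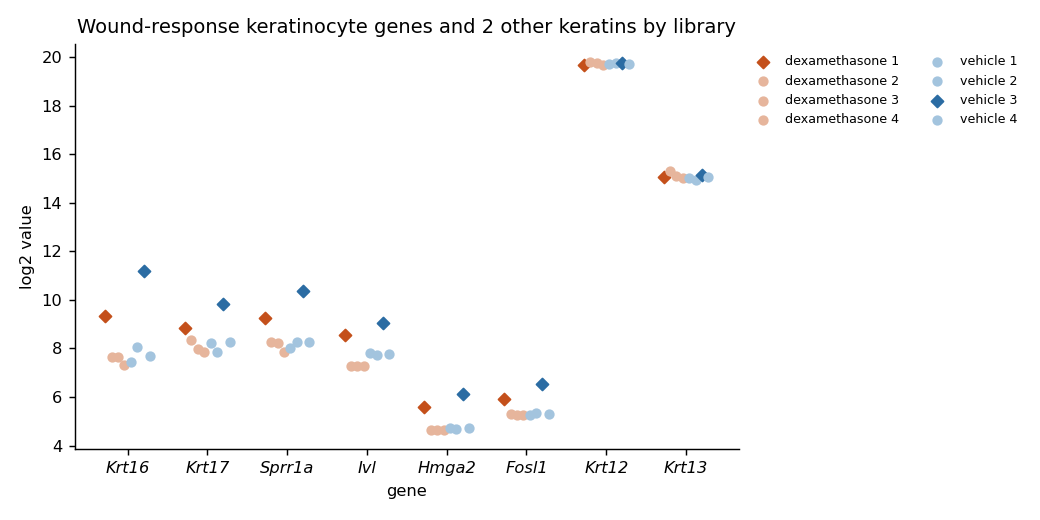
Log2 values (vertical axis) of 8 genes in each of the 8 libraries. Diamonds mark dexamethasone replicate 1 and vehicle replicate 3. These are the highest 2 of the 8 libraries for Krt16, Krt17, Sprr1a, Ivl, Hmga2 and Fosl1, and not for Krt12 or Krt13.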

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

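Of 117 named genes in 2 groups, 16 of 234 sets of 4 libraries had a single library whose gap to its nearest neighbour exceeded Dixon's critical share of the range. Chance flags about 1 in 20, or 11.7 of 234, so single entries carry little weight. The tests of the pattern below were all chosen after the results were seen.

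Vehicle replicate 3 was the isolated library in 6 of these sets: it was highest for Ddit4 (gap over range 0.872), Ctgf (0.896), Slc7a5 (0.838), Klf5 (0.898) and Slc3a2 (0.858), and lowest for Egf (0.906). Dexamethasone replicate 1 was isolated in 3: highest for Mrc1 (0.889) and Tnfaip2 (0.840), and lowest for Bmp7 (0.841). Dexamethasone replicate 3 was highest for Ddit4 (0.929) and Ticam1 (0.894) and lowest for Ptges3 (0.878). Vehicle replicate 4 was highest for Cldn8 (0.839) and Uhrf1 (0.931), and vehicle replicate 1 was highest for Zbtb16 (0.840) and lowest for Wnt5a (0.868). The sets of Slc7a5 and Slc3a2 belong to a list with no called member: both genes passed the test without vehicle replicate 3 (adjusted p of 0.005 and 0.001, limma).

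Apart from these entries, wound-response genes were raised in vehicle replicate 3 and dexamethasone replicate 1. The 17 tested genes of a list written after the values were seen had a median deviation from the other libraries of the same group of 0.64 in dexamethasone replicate 1 and 0.85 in vehicle replicate 3, and of -0.16 to -0.32 in the other 6. The pattern is wider than that list: 20 amino acid and ATF4 response genes, a list fixed in advance that includes Slc7a5 and Slc3a2 and shares no gene with it, deviated by 0.31 and 0.54 in these libraries (above all random lists) and by -0.05 to -0.23 in the other 6. In both lists a raised library enters the reference of the others in its group, so their negative values follow partly from its rise. Random lists were drawn gene by gene at like level, so lists of genes that vary together reach extreme percentiles easily. Standing above all random lists therefore carries little weight. The explanations below were tested on the wound-response list. A trend with the level of rows without a read is argued against, since each library differed in these genes from the library with the nearest such level, by medians of 0.52 and 0.88 (0.516 is the smaller). For vehicle replicate 3 that library was vehicle replicate 4, of its own group. For dexamethasone replicate 1 it was vehicle replicate 1, so the 0.52 also holds the group difference. The depth of single libraries is not given. In the 2 libraries, the 50 genes nearest in level to each member had median deviations of -0.00260 and -0.00879. Genes of like level were thus not raised in general. The highest median in 10000 draws of 1 such gene per member was 0.10. The values are normalized, which centres such medians, and the list was written after the values were seen. This comparison therefore cannot decide on depth. Conjunctival tissue in the pools stays open. A list of 12 conjunctival and limbal genes fixed in advance shares Krt16 and Krt6a with the wound-response list. It deviated by 0.020 in dexamethasone replicate 1 and 0.124 in vehicle replicate 3, above 78.83% and 99.99% of random lists. In the other 6 libraries it deviated by -0.139 (vehicle replicate 2, 0%) to 0.023 (dexamethasone replicate 2, 90.72%). Extreme percentiles were thus not limited to the raised libraries, and they cannot decide on such tissue. In the raised libraries, 8 conjunctival genes chosen later deviated by -0.066 and 0.083 (0.62% and 99.04%). The largest ratio to the wound-response deviation was 0.146. A bound of 0.5 on this ratio for the later list alone was used first and would have excluded such tissue. The second list and the demand that neither list exceed 95% of random lists in either library were added after these values were seen, because abundant conjunctival transcripts can hide a small share. Handling of the tissue before RNA extraction may have contributed and cannot be told apart from other events in the mice: the immediate-early list deviated by 0.125 in vehicle replicate 3 and 0.066 in dexamethasone replicate 1, and the labels describe no handling step that differed. The design gives no group for this pattern, so no biological explanation was tested.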

How the results depend on the processing

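The term for the level of rows without a read, the joint removal of 2 libraries and camera without its variance trend were chosen after seeing the data; the other alternatives were set before the data were examined. No gene called in the analysis as reported changed its direction in any gene-wise alternative. Of 119 named genes 86 kept their side of the threshold in every alternative in which they were tested. The stricter filter covered 113 of the 119. The replicate numbers do not pair the samples (correlations of same-numbered deviations from -0.31 to 0.19), and with a replicate block 1675 genes were called, 1620 of them shared, with an adjusted p of 0.0301 for the blood vessel list. With the level of rows without a read as a covariate, 1168 genes were called, 755 higher and 413 lower, and 23 named genes lost their call. The lens crystallin list then lost its call, with an adjusted p of 0.915 (camera) and a sign that turned to up. The cause was not tested. That list is also fragile otherwise: its adjusted p was 0.0422, and 0.0551 in camera without the variance trend, the version run first. It was the list whose call differed between these versions, and no list was called with an estimated correlation in either of them.

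With an estimated correlation the adjusted p (camera) was 0.103 for glucocorticoid receptor targets, 0.615 for matrix genes, 0.248 for clock genes and 0.865 for cell cycle genes. In the same order fry gave 0.000153, 0.0129, 0.00283 and 0.0767. The estimated correlations were 0.186, 0.071, 0.006 and 0.359, against the preset 0.01. That of the clock list lay below the preset, so a higher correlation is not why it lost its call. The blood vessel list passed without a filter (0.0327), with quantile normalization (0.0282) and with median centring (0.0455). The cause was not tested. Leaving out 1 library, or dexamethasone replicate 1 and vehicle replicate 3 together, gave 1411 to 2202 called genes, 918 to 1323 higher and 493 to 879 lower, and 3 to 5 with an absolute log2 fold change of at least 1. The adjusted p ranged from 0.00424 to 0.313 for the blood vessel list (below the threshold without dexamethasone replicate 1 or 3 or vehicle replicate 4) and from 0.00149 to 0.0921 for the cell cycle list (above it without vehicle replicate 1). Lists not called either way changed direction 14 times. Count tests with whole reads were not run, because the values are not counts. Depth limits cannot be given, and changes of genes with low values are understated.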

Other observations

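All tests in this part were chosen after the results were seen, except those on lists fixed before the data were examined. Of 22 tested cholesterol synthesis genes 11 fell and 1 rose, with a median log2 fold change of -0.19, and 15 fell adjusted over the list alone (adjusted p = 3.84e-06, camera; adjusted p = 0.865 with an estimated correlation and 0.0761 with fry). The fallers numbered 6 without dexamethasone replicate 2 or 4 or with no filter, and 4 with the level of rows without a read as a covariate, while the adjusted p in camera with the preset correlation stayed between 9.20e-08 and 7.31e-05 over the alternatives. This list also differed between libraries of a group, by 0.158 in vehicle replicate 3, 0.071 in dexamethasone replicate 1 and -0.125 in dexamethasone replicate 4, which is near the size of the change; without the first 2 of these libraries 12 fell, with a median of -0.18. Without dexamethasone replicate 4 the median was -0.16. Among the 11 were Stard4 (-0.26) and Mvk (-0.20). Wnt10a (0.39) rose, and Wnt5a (-0.35) and Dkk2 (-0.33) fell, within a Wnt list in which 5 of 26 rose and 3 fell (adjusted p = 0.711, camera). In the corneal endothelium list 4 of 13 rose and 3 fell, with Aqp1, a water channel gene, at -0.37 (adjusted p = 0.405, camera).

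Immediate-early genes rose in 8 of 31 cases and fell in 2, including Fosl2 (0.46), Fos (0.32) and Hspb1 (0.29) (adjusted p = 0.0348, camera; adjusted p = 0.865 with an estimated correlation), a call lost without dexamethasone replicate 1 (0.147), vehicle replicate 1 (0.0921) or vehicle replicate 4 (0.110), with quantile normalization (0.0509) or with fry (0.158). None fell without dexamethasone replicate 2, 3 or 4 or vehicle replicate 4, and 1 fell without vehicle replicate 2. In the TGF-beta and BMP list 7 of 28 rose and 1 fell (adjusted p = 0.0422, camera; adjusted p = 0.865 with an estimated correlation), lost without dexamethasone replicate 1 (0.122) or vehicle replicate 1 (0.0887) or 2 (0.137), with a stricter filter (0.0555), quantile normalization (0.0704), fry (0.0587) or the covariate (0.0558). The risers numbered 3 without dexamethasone replicate 2 or vehicle replicate 2, 4 without dexamethasone replicate 4 or vehicle replicate 4, with a replicate block or with no filter, and 2 with the covariate. Of 15 lens genes 4 fell, Crygb (-0.26), Crygd (-0.30), Crygc (-0.24) and Bfsp2 (-0.17) (adjusted p = 0.0422, camera, and 0.865 with an estimated correlation). The call of the list was lost without dexamethasone replicate 2 (0.313) or 3 (0.0825) or vehicle replicate 1 (0.0921) or 2 (0.0617). It was also lost with a stricter filter (0.358), quantile normalization (0.0581), limma without trend (0.0551), fry (0.284) or the covariate (0.915, with no clear direction). Without dexamethasone replicate 1, 7 fell, and 1 rose without vehicle replicate 2. Crygc lost its call in 10 alternatives, among them those without dexamethasone replicate 1, 2 or 3 or vehicle replicate 1, 2 or 4 (adjusted p of 0.059 to 0.086, limma). The lens list deviated by 0.30 in dexamethasone replicate 1 and by -0.19 in dexamethasone replicate 2. The macrophage and dendritic cell list had Mrc1 higher (0.23) and Cx3cr1 (-0.21), Ccr2 (-0.24) and Lyz2 (-0.23) lower (adjusted p = 0.288, camera). Ccr2 and Lyz2 lost their calls without vehicle replicate 4. Ccr2 also lost its call without dexamethasone replicate 3 or 4 or vehicle replicate 1 or 2 (adjusted p of 0.050 to 0.063, limma), and in 7 alternatives in all. The fallers numbered 6 without vehicle replicate 3 and 1 without vehicle replicate 4, and 2 rose without dexamethasone replicate 3. Basement membrane genes were looked at afterwards: 9 of 24 rose and none fell, with Papln at 0.83, Tinagl1 at 0.72, Col4a1 at 0.64 and Col4a2 at 0.60, and 5 rose without dexamethasone replicate 4, with quantile normalization or with the covariate.

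Replication genes were followed up with lists written after the data were seen. Of 33 replication and S phase genes 30 fell and 1 rose, with a median log2 fold change of -0.30. Their mean differed by -0.34 (SE 0.03 over libraries, 4 against 4). The list was written after falls of such genes had been seen, so its count and mean are no independent evidence; in the cell cycle list, fixed in advance, 12 of 32 fell. The 2 libraries with raised wound-response genes are argued against as the source, since the median was -0.299 without them, and so is a trend with the level of rows without a read (-0.315 with that level as a covariate). Depth is not given for single libraries. Genes nearest in level to the members had a median log2 fold change of -0.0122, so genes of this level did not fall in general. The lowest median in 10000 draws of 1 such gene per member was -0.079. The values are normalized, which centres such medians, and the list was written after the falls were seen. This comparison therefore cannot decide on depth. Fewer dividing cells in the pools would lower mitotic genes as well, and the median of 28 mitotic genes was 0.0449 (difference of means 0.04, SE 0.03). The mitotic list was also written after the data were seen, so it is no independent test of this explanation. An effect of dexamethasone on S phase genes is a hypothesis, found and examined on the same data.

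Xist, the RNA of the inactive X chromosome in females, stood at 9.20 to 9.29 in all 8 libraries of male mice, beside Y-linked genes such as Ddx3y at 10.18 to 10.46. A candidate explanation is that the values were shrunk toward a mean that included other libraries, which are not analysed here. At the lowest level of the table, -3.87, 694 rows showed 16 patterns: 8 with 1 library above the rest and 8 with none, as single reads in 8 further libraries would leave. Reads from female corneas are argued against, because Xist followed the level of rows without a read (Pearson r = 0.982, exact permutation p = 0.000223; Spearman rho = 0.976, permutation p = 0.000397; n = 8). Without the 2 libraries farthest from the median r was 0.977, and within groups it was 0.991 and 0.933 on 4 libraries each; 2 relations were computed, with an adjusted p of 0.000446, and Xist had no clear relation to the mean of 4 Y-linked genes (r = 0.229, rho = 0.048, permutation p = 0.583 and 0.935). The offset itself differed between the groups by -0.953 in units of 0.0001 log2 (two-sided exact permutation p = 0.114).

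Chance as the source of the group difference was examined by regrouping. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave 2218 or more called genes. The highest of the others gave 0. The share of 1 in 35 is under 0.05, which argues against a chance split. It is also the smallest share this design allows, so chance is not excluded. The other splits mix both treatments, which puts the treatment difference into their spread, so their 0 calls do not measure false calls.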
